A study of Bacillus subtilis with 2 samples.

How the data were processed

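RNA was sequenced from cultures of Bacillus subtilis strain BY212, described in the labels as an amylase-producing strain, at 16 h and at 64 h of a repeated batch fermentation in rich medium with renewed glucose. There was 1 library per time point. The series text places glucose additions at both hours, and whether cells were taken before or after them is not given in the sources used here. Per the labels' protocols, each culture was poured onto crushed frozen buffer with chloramphenicol, an inhibitor of translation. RNA was taken up with phenol and chloroform, ribosomal RNA was depleted with a bacterial mRNA enrichment kit, the remaining RNA was fragmented with magnesium, and libraries were built with a small RNA preparation set. Ribosome profiling of these cultures, named in the title of the series, was not analysed here.

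The authors deposited, for each library, a table of whole-number read counts per annotated feature, with ribosomal and transfer RNA features included and with no normalization. The submitters' processing notes name cutadapt 4.0, FastQC 0.73 and Bowtie2 2.4.2. The counting tool, the strand setting, the annotation and the genome build are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical copies cannot be separated, and no coordinates are given. Both tables list the same 4422 IDs in the same order. Gene symbols came from the RefSeq table of assembly ASM904v1 (B. subtilis 168), matched on locus tag for 4416 IDs. That table lists no older symbols. The 6 IDs with no name stayed out of scaling and comparisons. They held 5.21% of the reads at 16 h and 1.17% at 64 h, nearly all on the ID BSU41070. The gene amyM, which the strain was used to express per the series text, was matched to no ID and was not analysed here. Whether an ID with no name stands for it is not known.

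Depth differed between the libraries. The 16 h library held 913697 counts and the 64 h library 604478. Named features other than rRNA and tRNA held 498880 counts at 16 h and 127558 at 64 h. The median count over these 4300 features was 20 at 16 h and 2 at 64 h. Features with at least 20 counts summed over both libraries were called measured, which left 2289, of which 2228 were protein-coding. TMM factors (edgeR 4.0.16 in R 4.3.3) were computed over the measured features. After this scaling, 1 count was worth 1.39 CPM (TMM-scaled) at 16 h and 11.7 at 64 h. The floor of 3 counts that a count of 0 allows came to 4.17 CPM at 16 h and 35.1 at 64 h.

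With 1 library per time point no p-value, standard error or count of significant genes was computed, and no difference has a replicate check. The log2 ratio of a gene was taken as 64 h over 16 h after adding 0.5 counts scaled to library size. A fold is the ratio of scaled counts, given with the exact conditional (Clopper-Pearson) 95% interval of the 2 counts. A fold against 0 counts was computed against the floor of 3 counts in that library and is called a bound. This bound takes the count of the other library as exact, so the exact 95% interval reaches somewhat lower. All intervals and floors cover counting error only. The reads carry no stated molecular identifiers, so they are not known to be independent molecules. Shares carry exact Clopper-Pearson intervals.

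Before the data were examined, 52 gene lists of 1124 symbols in all were fixed, of which 111 symbols matched no named feature. Lists with at least 3 measured members numbered 48. For each, the median log2 ratio was ranked against 10000 random lists of the same size drawn from measured features in the same 10 bins of mean expression. A list was said to stand apart below percentile 2.5 or above percentile 97.5, which about 1 list in 20 reaches by chance if its genes vary independently. The 95% counting interval of a median came from 1000 Poisson draws of the counts. A gene may belong to several lists. Symbols known only under other names were not matched, so some list members were not counted.

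Genes named in the text were chosen by a rule fixed at the same time. It took the 12 highest and 12 lowest log2 ratios among protein-coding genes with 100 or more summed counts, the 5 protein-coding genes with the most counts in each library, up to 4 members of each described list with 50 or more summed counts (the 2 highest and 2 lowest), and a fixed set of regulators and marker genes. Genes outside the rule are said to be so.

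The alternatives were total-count scaling, the median of ratios (DESeq2 1.42.0 size factors), upper-quartile scaling, no filter on low counts, a filter at 100 summed counts, 5 counts added before the log, a counting interval wholly past 4-fold, and thinning of the 16 h library to the total of the 64 h library. Inclusion of the IDs with no name and restriction to protein-coding genes were added after the data were seen. The calculations were tested on simulated data drawn from the real shares and totals, with 2172 genes measured. All 50 genes simulated 8-fold higher at 64 h came out at least 4-fold higher, and 41 of 44 measured genes simulated 8-fold lower came out at least 4-fold lower. Of 1980 unchanged genes, 12 came out past 4-fold through counting error. Of 100 random lists of 20 unchanged genes, 6 fell outside percentiles 2.5 to 97.5. Most genes were simulated as unchanged, and counts varied by Poisson error alone. The simulation therefore tests neither the choice of scaling for the real libraries nor variation between cultures.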

Results

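Transcript levels were measured by RNA sequencing in Bacillus subtilis BY212, a strain used for amylase production, early (16 h) and late (64 h) in a repeated batch culture with renewed glucose. The comparison shows which transcripts differed in abundance between these culture times; each time point was sampled with 1 library, so every difference below is a difference between 2 libraries without a replicate check. The 16 h library held 913697 counted reads and the 64 h library 604478. Protein-coding genes took 47.9% of all reads at 16 h (95% interval 47.8 to 48.0) and 12.3% at 64 h (12.3 to 12.4). Reads on tRNA features made up 25% at 16 h and 54.6% at 64 h, and those on rRNA features 15.2% and 23.1%. Intervals throughout are 95% and cover counting error only.

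**Figure D1:**
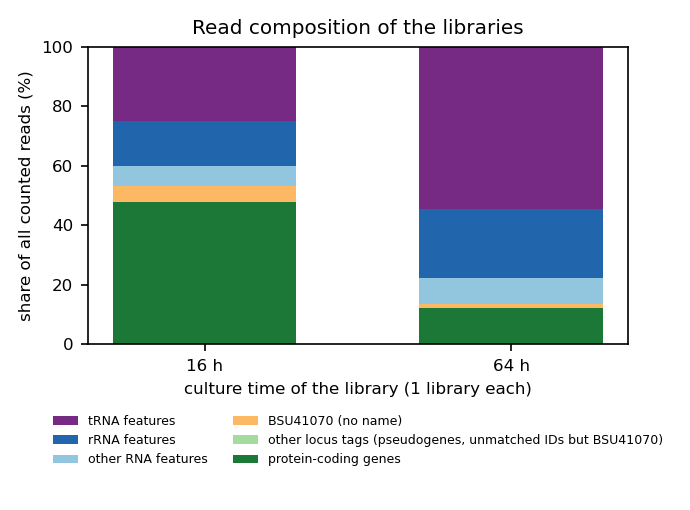
Share of all counted reads (%, y axis) by feature class in the 16 h and the 64 h library (x axis, 1 library each). Protein-coding genes (dark green) took 47.9% of reads at 16 h and 12.3% at 64 h, and tRNA features (purple) 25% and 54.6%.

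The comparison of 64 h with 16 h asks how the transcriptome of these cultures differed after repeated glucose additions. Of 2289 measured genes, 203 were at least 4-fold higher and 346 at least 4-fold lower at 64 h, relative to a scaling set by the bulk of genes. The counting interval lay wholly past 4-fold for 127 genes that were higher and 46 that were lower. Of the 346, 131 had no read at 64 h, and with these set at their bound 230 genes remained at least 4-fold lower. No measured gene lacked reads at 16 h. A count there is worth fewer CPM, so the filter on summed counts favours genes that are higher at 16 h. With the 16 h library thinned, 163 genes were at least 4-fold higher and 192 lower at 64 h. The rank correlation between the libraries was 0.53 (Spearman's rho across genes, which are not independent replicates). Scaling to total counts instead moved the median log2 ratio of all measured genes by -1.09 and gave 83 genes at least 4-fold higher (10.3% of those past 4-fold, against 37.0% in the main scaling) and 726 lower.

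Genes of acetoin breakdown and 2 of the 3 measured genes of gluconeogenesis were among those with the highest ratios at 64 h. The acetoin dehydrogenase genes acoA, acoB, acoC and acoL went from 31, 32, 14 and 20 reads at 16 h to 1157, 809, 703 and 543 at 64 h. After scaling acoA was 315-fold higher (220.4 to 465), acoC 423-fold (250.5 to 778), acoL 229-fold (147 to 378) and acoB 213-fold (149.7 to 314). The gene gapB, for the gluconeogenic glyceraldehyde-3-phosphate dehydrogenase, had 2 reads at 16 h and 461 at 64 h, a ratio of 1943 (535 to 16088). The gene pckA, for phosphoenolpyruvate carboxykinase, was 487-fold higher (283 to 919). Among protein-coding genes with 100 or more summed counts, the others of the 12 highest ratios were those of rgpA (1 read and 321 reads, ratio 2705, 482 to 107179), yhfH (109-fold, 81.5 to 148), ywcI (90.5-fold, 66.6 to 126), the catalase gene katA (70.9-fold, 49.6 to 104), and the sporulation genes spoIIB (50.6-fold, 29.6 to 92) and spoIIE (49.3-fold, 36.7 to 67.3).

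The 12 protein-coding genes with the lowest ratios, again among those with 100 or more summed counts, had no read at 64 h, so their folds are bounds. Genes of uridylate synthesis and uracil uptake were among them. The gene pyrD had 363 reads at 16 h and was at least 14.4-fold lower, pyrF at least 9.93-fold, the uracil permease gene pyrP at least 9.65-fold and pyrB at least 7.99-fold. The anaerobic regulator gene fnr was at least 7.99-fold lower, the nitrate reductase gene narI at least 5.97-fold, and cydD, for assembly of cytochrome bd, at least 4.87-fold. The others were pgdS (polyglutamate hydrolase, at least 7.75-fold), nadC (NAD synthesis, at least 7.63-fold), albF (subtilosin production, at least 6.01-fold), copO (at least 5.30-fold) and the chemoreceptor gene mcpA (at least 4.90-fold). The exact intervals, which also hold the counting error at 16 h, reached down to 11.6-fold for pyrD. Those of mcpA (3.93) and cydD (3.90) reached below 4-fold.

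**Figure D2:**
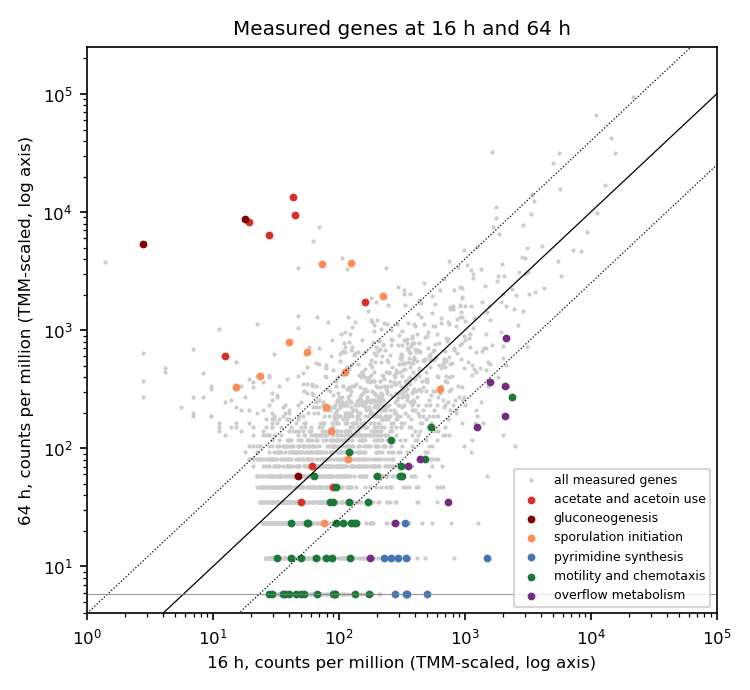
TMM-scaled CPM at 16 h (x) and 64 h (y) on log axes for the 2289 measured genes (grey) with 6 gene lists in colour; the solid line marks equal levels and the dotted lines 4-fold differences. Genes without a read at 64 h are drawn on the grey horizontal line, at the level of 0.5 counts; the acetoin genes and gapB and pckA lie far above the upper dotted line and all 10 pyrimidine genes below the lower one.

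Of the 48 gene lists with at least 3 measured members, 7 had a median above the central 95% of matched random lists and 14 a median below it. If listed genes varied independently, about 2.4 of 48 lists would lie outside by chance. Random lists drew genes singly, whereas many listed genes share operons and adjacent measured genes correlated at 0.49, so the chance number for such lists is larger than 2.4. These 21 medians kept their direction under each of the 3 other scalings. Another scaling moves all log2 ratios by nearly the same amount. The median shift was -1.09 for total counts, 0.093 for the median of ratios and -0.083 for the upper quartile. In the direction needed, no shift was large enough to change the sign of these medians, so this is no support. Changed filters reversed those of SigG forespore genes (-0.79 without a filter) and of cannibalism toxins and subtilosin (0.33 with 100 or more summed counts).

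**Figure D3:**
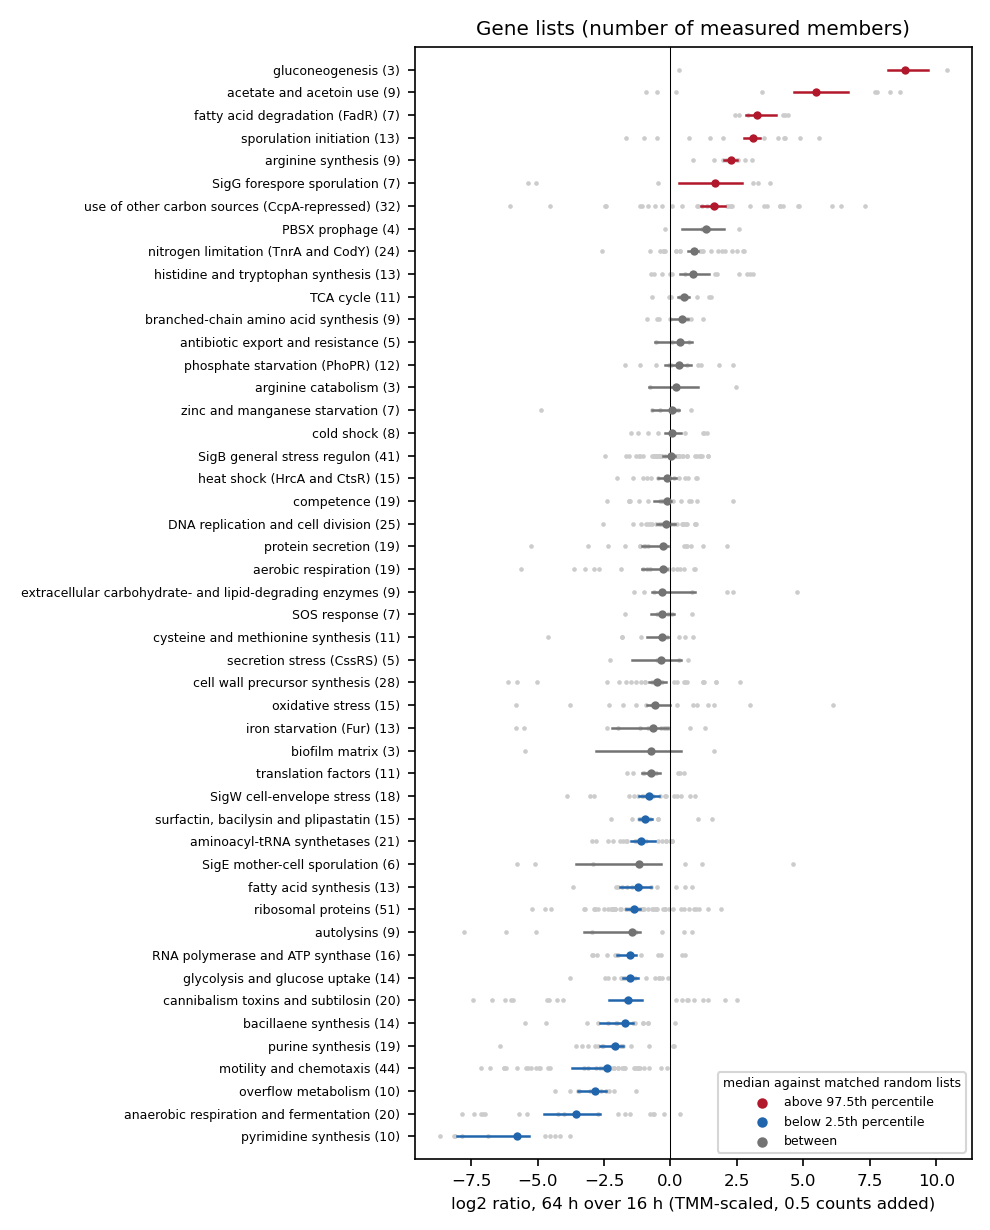
Log2 ratio of 64 h over 16 h (x axis) for the measured members (grey points) of each gene list (y axis, number of measured members in brackets), with the list median and the 95% counting interval of that median. Red medians lie above and blue ones below the central 95% of matched random lists; gluconeogenesis (8.83) and pyrimidine synthesis (-5.79) mark the ends.

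Central carbon metabolism differed in opposite directions by pathway. In the list of acetate and acetoin use, 6 of 9 measured genes were at least 4-fold higher at 64 h (median log2 ratio 5.47, 4.64 to 6.69), whereas acuC had a ratio of 1.15 (0.400 to 2.71) and acuA one of 0.519 (0.137 to 1.39). All 7 measured genes of fatty acid degradation were at least 4-fold higher (median 3.27, 2.84 to 3.95). Among them the electron transfer flavoprotein genes etfB and etfA were 22.1-fold (14.7 to 33.8) and 20.7-fold (12.4 to 35.7) higher, fadN 9.93-fold (5.82 to 17.1) and lcfA 7.57-fold (5.51 to 10.4). Of 66 named genes for the use of other carbon sources, repressed by CcpA when glucose is present, 32 were measured. Among these 15 were at least 4-fold higher and 4 at least 4-fold lower (median 1.63, 1.17 to 2.04). With the 2 genes lacking reads at 64 h at their bound, 2 were at least 4-fold lower. The ribose transporter gene rbsA had 2 reads at 16 h and 55 at 64 h (ratio 232, 61.2 to 1962), and the glycerol facilitator gene glpF was 99.4-fold higher (40.3 to 318). In the same list the mannitol uptake gene mtlA had 58 reads at 16 h and none at 64 h, at least 2.29-fold lower, and mtlD was 6.05-fold lower with 1 read at 64 h (1.04 to 244). The gene ccpA itself had a ratio of 0.936 (0.389 to 1.95).

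Glycolytic genes and genes of overflow metabolism were lower at 64 h. All 14 measured genes of glycolysis and glucose uptake had a ratio below 1 (median log2 ratio -1.52, -1.80 to -1.22), 4 of them by 4-fold or more. The glucose permease gene ptsG was 14.2-fold lower (5.53 to 52.5), the phosphoglycerate mutase gene pgm 5.48-fold (3.56 to 8.89) and gapA, the glycolytic counterpart of gapB, 4.36-fold (3.38 to 5.72). In contrast ptsH had a ratio of 0.936 (0.599 to 1.41) and pfkA one of 0.799 (0.478 to 1.27). In overflow metabolism 9 of 10 measured genes were at least 4-fold lower (median -2.82, -3.46 to -2.43). The acetate pathway genes pta and ackA were 21.0-fold (7.13 to 102) and 15.2-fold lower (2.68 to 605), with 3 reads and 1 read at 64 h. The pyruvate dehydrogenase gene pdhC had a ratio of 0.230 (0.156 to 0.329) and the butanediol dehydrogenase gene bdhA was 2.46-fold lower (1.95 to 3.16). The TCA cycle list did not stand apart (median 0.50, percentile 55.7; the median turned negative under total-count scaling). Within it, citZ was 2.89-fold (2.51 to 3.32) and the aconitase gene citB 2.74-fold higher (2.57 to 2.91), while icd was 1.61-fold lower (1.34 to 1.93) and odhA had a ratio of 0.969 (0.850 to 1.10).

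Genes for the start of sporulation were higher at 64 h and genes of the later stages were hardly measured. In the list of sporulation initiation, 7 of 13 measured genes were at least 4-fold higher (median log2 ratio 3.10, 2.77 to 3.37). The master regulator gene spo0A had 161 reads at 16 h and 165 at 64 h, and was 8.64-fold higher (6.91 to 10.8). The chromosome anchoring gene racA was 29.9-fold higher (23.6 to 38.2), whereas spo0M was 2.00-fold lower (1.35 to 3.06) and spo0B had 55 reads and 2 reads (ratio 0.306, 0.0362 to 1.16). For the mother-cell genes of SigE, 6 of 33 named members were measured and the median did not stand apart (-1.19, percentile 29.2; with genes lacking reads at 64 h at their bound it was 0.15). Of 39 named spore coat genes of SigK 1 was measured, and of 9 named SigF genes 2. In the list of SigG forespore genes, 7 of 38 named members were measured and the median stood apart (1.68, 0.32 to 2.68). Its members at least 4-fold higher were 3 spoVA genes, with spoVAD 10.2-fold (5.72 to 18.3) and spoVAF 8.85-fold higher (5.60 to 14). The other list members together had a summed ratio of 1.14 (0.723 to 1.72), and without a filter on low counts the list's median was -0.79.

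Nucleotide synthesis transcripts were lower and arginine synthesis transcripts higher at 64 h. All 10 genes of pyrimidine synthesis were at least 4-fold lower, also with the 4 genes lacking reads at 64 h at their bound (median log2 ratio -5.79, or -4.00 with these at the bound). Summed over the list, 3189 reads stood against 7, a 54.1-fold lower level (26.2 to 135). The regulator gene pyrR was 14.4-fold lower (3.93 to 119) and pyrE 19.6-fold (3.47 to 778). Of 19 genes of purine synthesis and uptake, 11 were at least 4-fold lower, or 10 with purE at its bound (median -2.08, -2.67 to -1.78). The gene purB was 12-fold lower (4.06 to 58.4) and purE, with 75 reads at 16 h and none at 64 h, at least 2.97-fold. The salvage gene xpt and the guanylate synthesis gene guaB had ratios of 1.11 (0.612 to 1.87) and 1.06 (0.767 to 1.43). All 9 genes of arginine synthesis had a ratio above 1 and 6 were at least 4-fold higher (median 2.28, 2.01 to 2.51). The gene argF was 8.50-fold (6.56 to 11), argD 7.04-fold (5.0 to 9.89) and argC 3.14-fold higher (2.20 to 4.40), and argH 1.79-fold (1.32 to 2.4), the last being lower under total-count scaling. The list of histidine and tryptophan synthesis did not stand apart (median 0.86, percentile 96.5; the median was negative under total-count scaling). There trpE was 8.74-fold (6.35 to 12) and trpC 8.07-fold higher (5.24 to 12.4). The reference annotation marks trpC as a pseudogene. In the same list hisZ had a ratio of 0.606 (0.296 to 1.11) and hisD one of 0.655 (0.275 to 1.34).

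The nitrogen limitation list lay at percentile 97.47, just short of standing apart (median 0.87, negative under total-count scaling). Of its 24 measured genes 5 were at least 4-fold higher and 1 at least 4-fold lower. The dipeptide transporter genes dppD and dppE were 6.86-fold (5.25 to 8.94) and 6.66-fold higher (5.47 to 8.09), nasF had a ratio of 0.583 (0.305 to 1.02) and the asparaginase gene ansZ was 6.53-fold lower with 1 read at 64 h (1.12 to 262). The gene glnA, for glutamine synthetase, was among the most abundant transcripts at both times, with 9410 and 1444 reads and a ratio of 1.29 (1.22 to 1.37) that fell below 1 under total-count scaling. The regulator gene codY had a ratio of 0.903 (0.522 to 1.47).

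Transcripts of the translation machinery were lower at 64 h, though not uniformly. Of 51 ribosomal protein genes, 42 had a ratio below 1 and 18 were at least 4-fold lower (median log2 ratio -1.38, -1.67 to -1.16). At the ends, rplL and rpsQ had 345 and 244 reads at 16 h and 1 each at 64 h, and were 40.9-fold (7.30 to 1622) and 29.0-fold lower (5.15 to 1148), whereas rpsU was 3.75-fold (3.06 to 4.57) and rpmA 2.68-fold higher (2.45 to 2.93). The aminoacyl-tRNA synthetase genes had a median of -1.11 (-1.50 to -0.60), with 17 of 21 below a ratio of 1. The genes tyrS and pheT were 8.54-fold (1.49 to 342) and 7.28-fold lower (2.45 to 35.6), with 1 and 3 reads at 64 h; trpS and cysS both had a ratio of 1.05 (0.487 to 2.04 and 0.368 to 2.47). Translation factors did not stand apart (median -0.74, percentile 3.97). Among them infA was 3.08-fold (1.95 to 5.16) and tsf 2.67-fold lower (1.57 to 4.94), prfA had a ratio of 1.44 (0.754 to 2.55) and lepA one of 1.28 (0.746 to 2.09), and the elongation factor gene tufA was 1.45-fold lower (1.29 to 1.62). The list of RNA polymerase and ATP synthase had a median of -1.52 (-2.02 to -1.29). Its ATP synthase genes atpH and atpG were 7.95-fold (2.68 to 38.9) and 7.75-fold lower (3.53 to 21.3), while rpoB and rpoC were 1.45-fold (1.29 to 1.63) and 1.36-fold higher (1.22 to 1.53), both lower under total-count scaling. The sigma factor gene sigA had a ratio of 0.772 (0.560 to 1.04), and the ribosome hibernation factor gene hpf was 1.98-fold lower (1.65 to 2.39).

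Motility and anaerobic respiration transcripts were lower at 64 h. All 44 measured motility and chemotaxis genes had a ratio below 1 and 28 were at least 4-fold lower (median log2 ratio -2.40, -3.72 to -2.31). Of these genes 14 had no read at 64 h, and with them at their bound the median was -1.57 and 15 were at least 4-fold lower. The flagellin gene hag went from 1691 to 23 reads and was 8.72-fold lower (5.79 to 13.8). The switch protein gene fliY was at least 3.84-fold lower, and fliE and flgC had ratios of 0.916 (0.284 to 2.30) and 0.775 (0.324 to 1.60). In the list of anaerobic respiration and fermentation, 12 of 20 genes were at least 4-fold lower (median -3.56, -4.75 to -2.65), or 11 with 6 genes lacking reads at 64 h at their bound (median -2.19). Apart from fnr, narI and cydD, the nitrite reductase genes nasD and nasE had ratios of 0.841 (0.614 to 1.13) and 1.30 (0.806 to 2.00). The list of aerobic respiration did not stand apart (median -0.30, percentile 20.4). In it the quinol oxidase genes qoxD and qoxC had ratios of 0.0786 (0.0213 to 0.203) and 0.107 (0.0486 to 0.204), while ctaF and qcrA were 1.88-fold (1.17 to 2.92) and 1.84-fold higher (1.24 to 2.67), both lower under total-count scaling.

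Among secondary metabolites, the list of cannibalism toxins and subtilosin split between its operons. Of its 27 symbols 23 matched a named feature, and a member known under another name would be missing from the values below. The most abundant matched member, skfA, was 5.61-fold higher at 64 h (5.34 to 5.89) and skfB 4.12-fold (3.67 to 4.62). In contrast albB and albF of the subtilosin operon had no read at 64 h and were at least 3.64-fold and 6.01-fold lower. The list's median was -1.61 (-2.32 to -1.08), while its summed reads were 2.52-fold higher (2.43 to 2.62), with a summed ratio of 0.962 without skfA, and its median was 0.33 with 100 or more summed counts. Bacillaene synthesis genes were lower (median -1.72, -2.67 to -1.41, or -1.19 with genes lacking reads at their bound), with 7 of 14 at least 4-fold lower, or 5 with these genes at their bound. Among the named members, pksM was 9.05-fold lower (3.50 to 33.4) and pksJ had a ratio of 0.150 (0.0598 to 0.311), while pksC and pksE both had one of 0.554 (0.175 to 1.35). The list of surfactin, bacilysin and plipastatin had a median of -0.96 (-1.18 to -0.68). The surfactin synthetase genes srfAA and srfAB were 1.37-fold (1.26 to 1.49) and 1.78-fold lower (1.61 to 1.98), ppsE 4.73-fold lower (2.14 to 13.0) and bacA 3.03-fold higher (1.52 to 5.70). Matrix genes were scarcely read: tasA had 39 reads and none, at least 1.54-fold lower, and 3 of 19 named members of the biofilm list were measured.

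Further lists that stood apart on the lower side were fatty acid synthesis and the SigW cell-envelope regulon. Fatty acid synthesis had a median log2 ratio of -1.20 (-1.90 to -0.72). There fabI had 116 reads and 1 read and was 13.8-fold lower (2.42 to 548), and the acyl carrier protein gene acpA was 4.18-fold lower (2.51 to 7.53), whereas accD was 1.77-fold higher (1.21 to 2.52; lower under total-count scaling). The SigW list had a median of -0.80 (-1.18 to -0.43), with ythP 16.4-fold lower (2.89 to 651) and yvlA 1.90-fold higher (1.18 to 2.95; lower under total-count scaling).

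The lists of the SigB regulon, heat shock, cold shock and protein secretion did not stand apart, and the medians of all 4 were negative under total-count scaling. The SigB general stress regulon, with 41 measured genes, had a median log2 ratio of 0.02 (-0.28 to 0.16), 21 genes above and 20 below a ratio of 1. The gene sigB was 2.05-fold lower (1.18 to 3.92) and gsiB had a ratio of 1.2 (0.865 to 1.62). In the heat shock list (median -0.13) clpX was 1.97-fold higher (1.58 to 2.43; lower under total-count scaling) and groEL 2.04-fold lower (1.57 to 2.69). Both cultures were chilled at harvest, so a response to chilling shared by both would not show in the ratios of the cold shock list. That list had a median of 0.04 (-0.19 to 0.40). Within it cspC was 2.57-fold (2.23 to 2.96) and cspD 2.37-fold higher (2.04 to 2.74), and cspB 1.46-fold (1.26 to 1.69), lower under total-count scaling. In protein secretion (median -0.26) the translocase gene secY was 8.59-fold lower (5.09 to 15.8), secA had a ratio of 0.845 (0.663 to 1.06), and the foldase gene prsA was 2.01-fold lower (1.31 to 3.24). The quality-control protease genes htrA and htrB, controlled by CssRS, were 1.26-fold (1.14 to 1.40) and 1.58-fold higher (1.42 to 1.75), both lower under total-count scaling. Of the extracellular proteases wprA alone was measured, with 5243 and 409 reads (1.52-fold lower, 1.38 to 1.69); aprE had 2 reads in each library. The native amylase gene amyE was 28.0-fold higher at 64 h (18.9 to 42.4). The regulator genes degU, sinR and abrB were 2.92-fold (2.16 to 3.89), 3.11-fold (1.67 to 5.54) and 2.57-fold higher (1.43 to 4.42).

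The ID BSU41070, which has no name and was not ranked here, held 47484 reads at 16 h and 7028 at 64 h. At both times this was more than any gene named below. Among named genes, the most abundant protein-coding transcripts overlapped in part. At 16 h they were liaD (11203 reads), glnA, veg (8140), srfAA (6723) and srfAB (5983). At 64 h they were ykoJ (2780 reads), liaD (2709), skfA (2689), spoVG (2213) and glnA. Of these, ykoJ was 19.7-fold (18.4 to 21.1) and spoVG 5.21-fold higher (4.94 to 5.49), liaD 2.04-fold higher (1.95 to 2.13; lower under total-count scaling) and veg 1.15-fold lower (1.07 to 1.23). The 10 most abundant named features other than rRNA and tRNA took 19.8% of the reads of that class at 16 h (19.7 to 19.9) and 49.5% at 64 h (49.2 to 49.7), and 6 features were in both sets.

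The other lists with a median did not stand apart either. Positive medians were those of the PBSX prophage (1.32, 4 measured genes), branched-chain amino acid synthesis (0.45), antibiotic export and resistance (0.34), phosphate starvation (0.34), arginine catabolism (0.22) and zinc and manganese starvation (0.05). Of these, that of PBSX alone stayed positive under total-count scaling (0.23). Negative medians were those of autolysins (-1.46), biofilm matrix (-0.72, 3 measured genes), iron starvation (-0.65), oxidative stress (-0.57), cell wall precursor synthesis (-0.52), secretion stress (-0.37), cysteine and methionine synthesis (-0.34), extracellular carbohydrate- and lipid-degrading enzymes (-0.30), the SOS response (-0.30), DNA replication and cell division (-0.16) and competence (-0.14). Median and summed reads differed in sign for several lists in the main scaling. With negative medians, the summed ratio was 3.51 for protein secretion (3.42 to 3.60) and 2.14 for oxidative stress (2.00 to 2.28). It was 2.13 for cell wall precursor synthesis (2.01 to 2.25) and 1.37 for secretion stress (1.27 to 1.47). Further such sums were 1.26 for SigE genes (0.923 to 1.70), 1.13 for extracellular degrading enzymes (0.999 to 1.27), 1.08 for heat shock (0.985 to 1.18) and 1.04 for DNA replication (0.954 to 1.13). Zinc and manganese starvation had a summed ratio of 0.916 (0.739 to 1.13) and a positive median. From SigE genes onward the intervals include 1, so no difference in direction is shown there. Nor is it for secretion stress, whose median had an interval of -1.44 to 0.40. Under total-count scaling the medians of all lists just named were negative. Their sums were below 1 except that of protein secretion (1.62), so for the others the difference in sign was gone. In a check chosen after these values were seen and made in the main scaling, single abundant members set several but not all of these sums. Without scr, the RNA of the signal recognition particle, the summed ratio of protein secretion was 0.498, and without glmS that of cell wall precursor synthesis was 0.982. Without their most read member it was 0.971 for heat shock, 0.888 for DNA replication and 1.05 for zinc and manganese starvation, and for oxidative stress without katA it was 1.62. It was 1.49 for secretion stress, 1.08 for SigE genes and 2.05 for extracellular degrading enzymes, which kept their side of 1.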

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

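All tests in this part were chosen after the results were seen. Reads on 1 ID without a name and on the tRNA and rRNA features, all outside the comparisons, lay far above the 3 counts that a count of 0 allows. The ID BSU41070, which has no name in the reference table, had 47484 reads at 16 h and 7028 at 64 h. On the scaling of the named genes its log2 ratio was 0.32, and it was lower under total-count scaling.

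Reads on tRNA features numbered 228502 at 16 h and 330095 at 64 h, and reads on rRNA features 138702 and 139755. Protein-coding reads per rRNA or tRNA read were 7.51-fold lower at 64 h. Whether weaker rRNA depletion at 64 h contributed is not settled. All tRNA, which a kit directed at large rRNA leaves in place, was higher against rRNA by 0.52 on the log2 scale (0.51 to 0.53, counting error only). Single features set this rise: reads of trnD-Trp, trnQ-Arg and trnS-Leu1 went from 75017, 12452 and 7692 to 157490, 36246 and 26011. Those of trnSL-Val2 and trnD-Ser fell from 26179 and 16000 to 9208 and 8308. The ratio depends on which tRNA features are counted, so it cannot decide. The protein-coding share of all reads, 47.9% at 16 h and 12.3% at 64 h, was not lower through 1 dominant feature alone. The feature trnD-Trp took 8.21% and 26.1% of the reads, yet without it that share was still 3.13-fold lower (52.2% against 16.7%). A lower amount of mRNA per stable RNA in the cells at 64 h and a difference in library preparation cannot be told apart, since each time point has 1 library.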

How the results depend on the processing

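The settings with IDs with no name included and with protein-coding genes only were chosen after seeing the data. The 64 h library limits most values: the median measured gene had 67 reads at 16 h and 7 at 64 h, and when the reads of each library were split at random in 2, log2 ratios of the parts correlated at 0.69 across genes (0.86 for genes with 100 or more summed counts). The counts of genes at least 4-fold higher and lower, 203 and 346, became 83 and 726 under total-count scaling. That total includes small RNAs. Measured features held 489368 reads at 16 h and 125697 at 64 h, of which protein-coding genes held 428788 and 72818. Over protein-coding genes alone the TMM factors lay nearer those of total-count scaling (0.8337 against 0.6797 at 64 h, with 1 for total count). Features other than protein-coding genes thus account for part of the shift, and the rest was not tested. The gene counts were 218 and 325 with the median of ratios and 191 and 361 with the upper quartile. TMM factors were computed anew wherever the set of genes changed. Without a filter on low counts, and so with more genes tested, the counts were 376 and 869. With 100 or more summed counts, and so with fewer genes, they were 96 and 141. With the counting interval wholly past 4-fold they were 127 and 46, and with the deeper library thinned, which leaves fewer genes above the filter, 163 and 192. With 5 counts added they were 175 and 243. They were 204 and 347 with IDs with no name included and 192 and 344 with protein-coding genes only. The rank correlation of 0.53 became 0.77 without a filter and 0.32 with 100 or more summed counts; the filter selects on the sum of both libraries. The share of the 10 most abundant features, 19.8% and 49.5%, was 36.4% and 68.8% over all features.

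Of the 21 lists that stood apart, all kept their direction under the scalings, with 5 counts added and with protein-coding genes only. For the scalings this was given by the size and direction of their shifts and is no support. SigG forespore genes reversed without a filter (-0.79), and cannibalism toxins and subtilosin with 100 or more summed counts (0.33); that filter left 11 of 48 lists with fewer than 3 members. Among named genes with a counting interval wholly above a ratio of 1, log2 ratios that turned negative under total-count scaling were those of liaD (-0.087), glnA (-0.74), cspB (-0.57), htrA (-0.78), htrB (-0.46), rpoB (-0.57), rpoC (-0.67), lytE (-0.31), clpX (-0.14), clpC (-0.44), ilvA (-0.32), argH (-0.27), pstS (-0.056), ctaF (-0.20), qcrA (-0.23), bacB (-0.056), lexA (-0.30), ftsZ (-0.15), parE (-0.17), accD (-0.29) and yvlA (-0.19). As shares of protein-coding reads alone, liaD, cspB and htrB rose (2.56% to 3.63%, 0.294% to 0.299% and 0.515% to 0.565%). The shares of glnA and htrA fell (2.15% to 1.93% and 0.669% to 0.588%). Shares of the other genes just listed are not given here. No paired analysis was possible because each time point has 1 library, and no library could be left out for the same reason.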

Other observations

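The tests and the genes of this part were chosen after values were seen. Small structured RNAs held most reads of the named features other than rRNA, tRNA and protein-coding genes. The tmRNA gene ssrA, which rescues stalled ribosomes, went from 18235 to 32531 reads and was 15.0-fold higher at 64 h (14.8 to 15.3). The 6S RNA genes ssrSB and ssrSA were 6.10-fold (5.89 to 6.31) and 3.50-fold higher (3.26 to 3.76), the signal recognition particle RNA gene scr 4.39-fold (4.27 to 4.51) and the RNase P RNA gene rnpB 2.93-fold (2.82 to 3.04). On this scaling, set by the bulk of genes, the most read rRNA features were also higher. The feature rrnE-16S was 8.03-fold, rrnD-5S 8.93-fold, rrnB-16S 9.68-fold and trnD-Trp 17.7-fold higher. The ratios of ssrSB, ssrSA, scr and rnpB were thus below those of these rRNA features, and ssrA rose less than trnD-Trp. Depletion of rRNA may have differed between the libraries, so this does not show a lower level of these RNAs.

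Genes of purine breakdown and peptide transport were also higher at 64 h in sum. The puc genes of purine breakdown had 544 and 387 reads, a summed ratio of 6.0 (5.25 to 6.84). The dpp, opp and app genes of peptide transport had summed ratios of 5.30 (4.77 to 5.88), 4.96 (4.17 to 5.89) and 4.36 (3.80 to 5.0), and the opuC genes of osmoprotectant uptake one of 4.15 (3.66 to 4.69). Without the most read gene of each, these ratios were 4.83 for dpp, 2.77 for opp, 3.45 for app and 3.26 for opuC. The nad genes had 702 reads at 16 h and 3 at 64 h, a 27.8-fold lower level (9.46 to 135). Within the list of histidine and tryptophan synthesis, the trp genes had a summed ratio of 5.88 (5.03 to 6.87) and the his genes one of 0.998 (0.797 to 1.24). The skf operon had a summed ratio of 4.56 (4.37 to 4.76), most of its reads being those of skfA and skfB. Its 7 genes ranged from -1.52 to 2.49 on the log2 scale (median 0.88), and without skfA the summed ratio was 2.56. The sbo-alb operon was 27.8-fold lower in sum (17.8 to 46.2).

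Neighbouring genes offer a check against counting noise alone. They come from the same libraries and can share operons, so they cannot stand in for replicates. Log2 ratios of adjacent measured genes correlated at 0.49 (1656 pairs), of genes 5 apart at 0.18 and of genes 50 apart at 0.02, across genes that are not independent replicates.

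The spoVA genes, listed as SigG forespore genes, were 10.7-fold higher at 64 h in sum (8.02 to 14.2). SigG activity in forespores is argued against as the whole reason by the other SigG list members, whose summed ratio was 1.14 (0.723 to 1.72). The spoVA genes follow the spoIIA operon on the chromosome, and spoIIAA and spoIIAB were 15.1-fold higher (11.2 to 20.6). Transcription from the neighbouring spoIIA promoter into spoVA would have to cross sigF, which had 1 read in both libraries together. This goes against it unless sigF is missing from this strain, which was not tested, so it stays open.

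Between these genes lies sigF, the last gene of the spoIIA operon, with 1 read in both libraries together against a mean of 96.5 for spoIIAA and spoIIAB. A sigF transcribed too weakly to be seen and a gene missing from this strain would both leave about this 1 read, so the counts of sigF alone cannot tell them apart, and the labels record no such absence. Weak transcription of sigF and a transcript running from spoIIA into spoVA exclude each other, and neither was shown. Of 7 extracellular protease genes, nprE, epr, bpr, mpr and vpr had no read in either library, nprB had 1 and aprE 4 in total, while 11.9% of protein-coding genes had no read in either. For 5 of these 7 a neighbouring gene had 20 or more reads, so missing genes and low expression cannot be told apart from read counts alone. The neighbour of vpr is ywcI, which was 90.5-fold higher at 64 h (66.6 to 126).

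After the lowest and highest ribosomal protein genes had been seen, of which rplL and rpsQ lie in the large cluster (BSU01020 to BSU01500) and rpsU and rpmA elsewhere, the hypothesis was that genes of the cluster were lower than the others. The medians were -2.09 for 32 genes in the cluster and -0.21 for 19 elsewhere, a difference of -1.87 on the log2 scale that lay below all 10000 random splits of these genes. Summed reads were lower in the cluster (ratio 0.344, 0.317 to 0.372) and higher elsewhere (1.53, 1.44 to 1.62), the latter turning lower under total-count scaling and being 1.03 without rpmA. These 4 genes are part of the comparison, so it is no independent test. Genes are not independent replicates, and the cause was not tested.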
